A study of Arabidopsis thaliana and Mus musculus and Danio rerio with 14 samples.

How the data were processed

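Genomic DNA of 14 libraries was sequenced after bisulfite treatment on an Illumina/Solexa Genome Analyzer, per the labels' protocols. The deposited files, 1 per sequencing lane and 21 in all, hold 1 line per observed cytosine of a read, with the sequence name, strand, coordinate and a call that the authors made, M for methylated or u for unmethylated. These deposited calls are in none of the usual units, and they were counted as observations. The aligner, the read filters and the treatment of duplicate reads are not given in the sources used here. The genome builds are those in the file names: TIGR5 for Arabidopsis shoots, TAIR9 for the 3 Arabidopsis flower libraries, TIGR5.0 for rice, JGI1.1 for poplar, JGI3.1 for Chlamydomonas, JGI2.0 for Ciona, Baylor2 for the honey bee, Sanger Zv7 for zebrafish and NCBI37 for mouse. Coordinates were shifted from the 0-based coordinates of the files to 1-based ones.

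Groups, the comparisons of levels, the tests of mutants against wild type and the rule for named regions were chosen before the data were examined, as were the alternatives except those named as added. Added after the data were seen were the window test of met1 against vim1 vim2 vim3, the overlap of the windows of both mutants, the grouping of windows by wild-type level, the values along chromosomes and the comparison of lanes by window. Each group held 1 library, so no test between samples was possible, and lanes of a library were pooled as technical runs. Nuclear sequences were used for all comparisons, and chloroplast and mitochondrial sequences were kept apart. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.

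No genome sequence was at hand, so the context of a cytosine was deduced from the cytosines observed in all libraries of the same build. A CG site had an observed opposite-strand cytosine at the next base. A CCG site had an observed cytosine of the same strand at the next base and an observed opposite-strand cytosine at the base after. A CWG-like site, called CWG in the results, had an opposite-strand cytosine 2 bases on and no cytosine observed between. A CCC site had observed cytosines of the same strand at the next 2 bases. CHG joins CCG and CWG, and CHH was measured in CCC alone. This was tested on simulated data, where 100% of deduced CG, CCG and CCC sites and 99.16% of deduced CWG sites had the deduced context. The 100% follows from the rules, since the simulated reads held no misplaced cytosines, so only the CWG value could have come out otherwise. Sites are recognised only where both strands were read, which favours well covered places. Levels were therefore also weighted: the level was computed in 3 strata of the number of opposite-strand cytosines observed within 30 bases (0 to 3, 4 to 8, and 9 or more), and each stratum was weighted by its share of all nuclear observations. In simulated data with a true CG level of 52.04%, the pooled level was 64.32% and the weighted level 60.59%, so the weighting corrects only part of the error.

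A methylation level is the percent of observations called methylated, with an exact Clopper-Pearson 95% interval. Differences and their standard errors come from a block jackknife over 1-Mb blocks, and no p-value was computed for them. The Clopper-Pearson intervals and the exact tests of windows treat each observation as independent, which duplicate reads are not.

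Windows of 2 kb in the flower libraries, and of 100 kb in the uhrf1 comparisons, were compared by Fisher's exact test, two-sided, where both libraries had at least 20 observations. A window was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 20 percentage points. For uhrf1, the methylated share of all cytosines in 1-Mb windows with at least 1000 observations was added after the data were seen, with no minimum difference. On simulated data with 50 changed windows per size and direction, the vim1 vim2 vim3 test in CG recovered 98% of falls of 60 points and 50% of falls of 30 points, with 2 wrong calls in 1988 windows. The met1 test in CHG recovered 92% of falls of 60 points and 18% of falls of 30 points, with 0 wrong calls in 3456 windows. In 1-Mb windows, the zebrafish test recovered 100% of falls of 6 points and 24% of falls of 2 points, with 6 wrong calls in 1130 windows, and the mouse test recovered 100% of falls of 2 points and 30% of falls of 1 point, with 3 wrong calls in 2532 windows. The overlap of both mutants among windows with at least 20% methylation in wild type was added after the data were seen, since windows below that level cannot fall by the minimum difference.

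Regions were named by a fixed rule: per comparison the 3 windows with the largest fall and the 3 with the largest rise among called windows, and per species the 3 most and the 3 least methylated 5-kb windows with at least 100 CG observations. Where fewer windows met the rule, all were named. In the 1-Mb windows of the uhrf1 comparisons, windows were named by their ratio after the data were seen. For the distribution of methylation, 5-kb windows with at least 20 CG observations were counted. Neighbouring CG sites of a strand were compared up to 2 kb apart, and the 2 strands of a site by drawing 1 call per strand. Windows were ranked into quintiles by their number of recognised CG sites.

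Added alternatives were the weighting by opposite-strand coverage, CG sites observed in both libraries, all cytosines in windows, ranking by the share of CG sites and at most 10 observations per site for strand agreement. The alternatives changed 1 choice at a time: counting each site once, a coverage minimum of 4, an upper coverage limit of 10 times the median, single lanes, subtracting background, contexts from each library alone, other window sizes, other minimums of observations and of difference, and thinning the deeper library. Background was the chloroplast level over all cytosines in land plants and the CCC level in animals, and Chlamydomonas was not corrected.

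Gene bodies, exons and introns, genes changed and the fixed gene lists were left out. The only gene table at hand is of assembly TAIR10.1, and the files use TAIR9 and other builds, so no gene was assigned to a coordinate. Contexts from a reference were left out for want of a genome.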

Results

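DNA methylation of single cytosines was measured by bisulfite sequencing in 14 libraries of plants, an alga and animals. Bisulfite turns unmethylated cytosines into bases read as T, while methylated cytosines are still read as C. The plants were Arabidopsis shoots and flowers, rice leaves and poplar leaves, and the alga was Chlamydomonas in vegetative growth. The animals were Ciona (a sea squirt), an immature male honey bee, zebrafish embryos, mouse embryos and mouse embryonic stem (ES) cells. The mutants were Arabidopsis met1 flowers, which lack a methyltransferase that copies CG methylation, Arabidopsis vim1 vim2 vim3 flowers, and uhrf1 zebrafish embryos and mouse ES cells. VIM proteins in plants and UHRF1 in animals bind methylated CG sites and are needed for this copying. Each group held 1 library, so no value has a replicate error. The intervals given cover counting error or, where they come from a jackknife, variation between parts of the genome within a library.

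Depth was low in every library, with mean coverage of covered nuclear cytosines between 1.02 in wild-type zebrafish embryos and 2.66 in Chlamydomonas. The Arabidopsis libraries held 11778106 nuclear cytosine observations in shoots, 11712312 in wild-type flowers, 8400502 in vim1 vim2 vim3 flowers and 10026691 in met1 flowers. Rice leaves held 6755985 observations, poplar leaves 4892022 and Chlamydomonas 14575567. The invertebrates held 5671625 observations in Ciona and 21244341 in the honey bee. Zebrafish held 2092242 observations in wild-type embryos and 2356167 in uhrf1 embryos. Mouse held 5578803 observations in embryos, 12958451 in wild-type ES cells and 10047807 in uhrf1 ES cells. A cytosine was recognised as a CG site only where the cytosine of the opposite strand had also been read. Between 0.0949% of nuclear observations in uhrf1 ES cells and 6.66% in vim1 vim2 vim3 flowers therefore fell on recognised CG sites.

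Wild-type genomes differed widely in CG methylation, and the question was how its level and pattern vary between plants and animals. The vertebrates carried the most, with 83.1% of CG observations methylated in zebrafish embryos, 81.9% in mouse ES cells and 77.1% in mouse embryos. Rice leaves reached 66.9% and poplar leaves 67.6%, above Arabidopsis flowers at 31.3% and Arabidopsis shoots at 21.1%. Chlamydomonas carried 42.7%, Ciona 35.6% and the honey bee 2.26%. The honey bee nucleus still exceeded its own mitochondrial sequence, where 0.205% of 48333 CG observations were methylated. The exact Clopper-Pearson 95% intervals were 82.0 to 84.2% in zebrafish, 81.2 to 82.5% in mouse ES cells and 2.22 to 2.30% in the honey bee. The levels of Arabidopsis flowers, poplar, rice and Chlamydomonas depended on which sites were used. At sites with at least 4 observations, flowers reached 62.8% and rice 62.3%, so the place of flowers below rice did not hold there, while poplar had 97.6%, Chlamydomonas 59.6% and shoots 19.1%. Mouse ES cells had 73.9% there, from 234 observations, so their place above poplar did not hold either. Weighted to the opposite-strand coverage of all observations in the library, poplar had 46.5%, rice 53.0% and Chlamydomonas 8.57%, so the place of Chlamydomonas between rice and Ciona did not hold. The same weighting gave 78.7% in zebrafish embryos, 83.5% in mouse ES cells, 26.9% in Arabidopsis flowers and 35.7% in Ciona.

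CCG and CWG methylation was highest in the plants and the alga, and CWG calls also exceeded CCC calls in zebrafish, mouse and Ciona. In poplar leaves, 56.4% of CCG observations and 33.6% of CWG observations (W is A or T) were methylated. Rice leaves carried 28.8% in CCG and 20.8% in CWG, and Arabidopsis flowers 9.99% and 10.2%. Arabidopsis shoots carried 4.85% in CCG and 5.72% in CWG, and Chlamydomonas 7.14% and 5.99%. In CCC, the only CHH class that could be recognised, the level was 2.83% in Chlamydomonas, 2.60% in rice, 0.943% in Arabidopsis flowers, 0.741% in poplar and 0.382% in Arabidopsis shoots. The chloroplast sequence of land plants gives the background of calls, and its CCC level was 0.450% in Arabidopsis flowers and 0.453% in poplar. Weighted to opposite-strand coverage, poplar fell to 23.5% in CCG and 22.8% in CWG, and rice to 13.9% and 14.6%. The excess of CCG over CWG in rice thus did not hold. Chlamydomonas, weighted likewise, had 7.15% in CCG and 3.95% in CWG. Its unweighted CCC level was 3.16% in lane 1 and 2.49% in lane 2. Among the animals, the CWG level was 2.55% in zebrafish embryos, 1.77% in mouse ES cells, 0.452% in Ciona, 0.423% in mouse embryos and 0.179% in the honey bee. The CCC level was 0.736% in zebrafish embryos, 0.483% in mouse ES cells, 0.220% in mouse embryos and 0.0953% in Ciona. In simulated data 99.16% of deduced CWG sites had that context. Others can be CG sites whose opposite-strand cytosine was not read, and their share in these libraries was not measured. The excess of CWG over CCC calls in animals is therefore not shown to be CWG methylation. The honey bee CCC level of 0.224% was not distinguishable at this depth from the 0.195% of its mitochondrial sequence, whose interval ran from 0.114 to 0.312%.

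**Figure D1:**
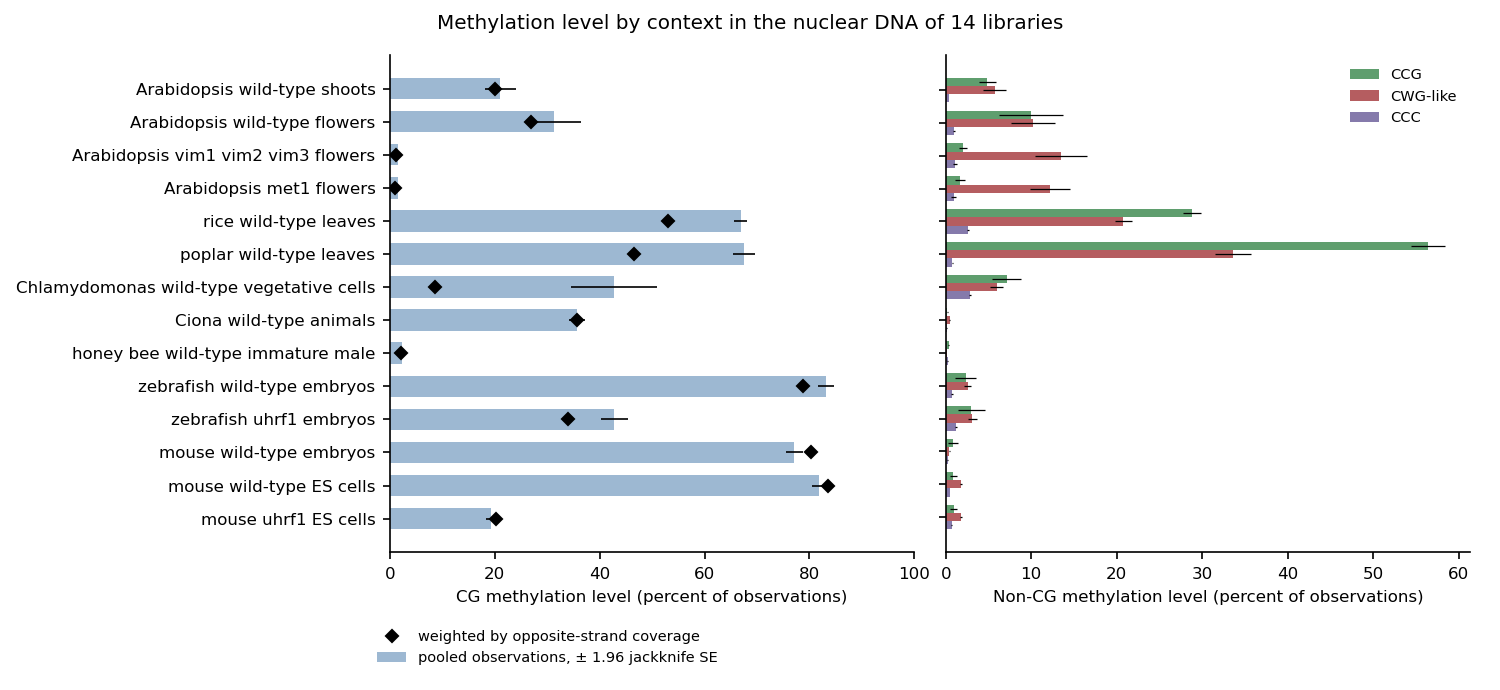
Methylation level of nuclear cytosines (percent of observations called methylated) in 14 libraries, in CG (left) and in CCG, CWG and CCC (right). Bars are pooled levels with 95% jackknife intervals and diamonds the CG level weighted by opposite-strand coverage, with bars from 1.45% (met1 flowers) to 83.1% (wild-type zebrafish embryos) and diamonds from 1.01% (met1 flowers) to 83.5% (wild-type mouse ES cells).

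Most Ciona windows of 5 kb were either low or high in CG methylation. Of 1160 Ciona 5-kb windows with at least 20 CG observations, 68.8% had under 20% CG methylation and 15.4% had over 80%, leaving 15.8% between these limits. In 100-kb windows 71.4% lay between the limits and 4.58% over 80%, and among 20 windows of 5 kb with at least 50 observations 30% lay between. Arabidopsis flowers had 54.2% of 16654 windows under 20%, 35.9% between the limits and 9.94% over 80%. In the honey bee, 98.1% of 9800 windows lay under 20% and 8 windows lay over 80%. Poplar and rice windows were nearly all highly methylated, with 99.1% of 223 and 95.1% of 183 windows over 80%. These poplar and rice windows were few and densely read, and in 100-kb windows the shares over 80% were 77.7% and 35.3%. In Chlamydomonas 55.4% of 897 windows lay under 20% and 8.25% over 80%. Zebrafish and mouse had too few windows with 20 CG observations for this count.

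**Figure D2:**
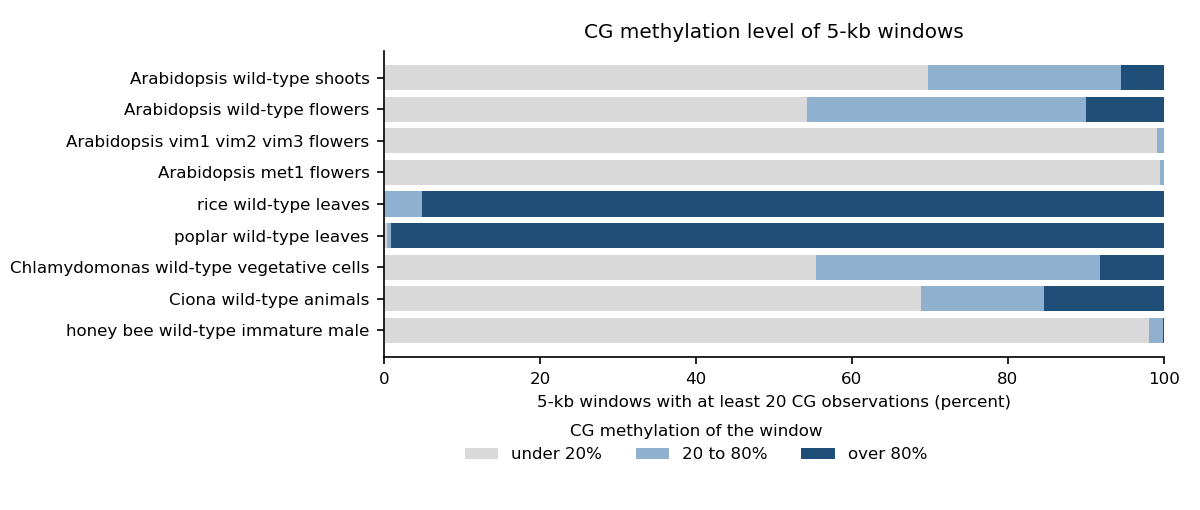
Share of 5-kb windows (percent, x axis) with under 20%, 20 to 80% and over 80% CG methylation, per library, among windows with at least 20 CG observations. Ciona has 15.4% of its windows over 80%, and met1 flowers have 99.5% under 20%.

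Single windows showed how far the extremes lay apart. Among Arabidopsis flower windows of 5 kb with at least 100 CG observations, the most methylated started on chromosome 3 at 11930001 (98.2%), on chromosome 1 at 15660001 (98%) and on chromosome 4 at 4990001 (97.46%), in TAIR9 coordinates. The least methylated of these 103 windows started on chromosome 5 at 18575001 (8.49%), on chromosome 1 at 29300001 (9.62%) and on chromosome 2 at 3365001 (30.8%). In Chlamydomonas, in build JGI3.1, the most methylated started on scfld0037_ at 590001 (97.1%), on scfld1062_ at 1 (96.1%) and on scfld0005_ at 2130001 (94.9%). The least methylated Chlamydomonas windows carried 0 methylated calls and started on scfld0087_ at 170001 (of 268 observations), on scfld0013_ at 1570001 (of 215) and on scfld0040_ at 680001 (of 184). A count of 0 in these allows levels of up to 1.37%, 1.70% and 1.99%. The 4 poplar windows, in build JGI1.1, started on scaf00214 at 160001 (98.3%), scaf00196 at 155001 (97.8%), scaf00190 at 345001 (97.3%) and scaf00456 at 20001 (95.2%). Ciona had 2 such windows, in build JGI2.0, on scaf7047 at 1 (1.79%) and on 3q at 2560001 (0 of 187, which allows up to 1.95%). The honey bee had 6 such windows, in build Baylor2, and those named by the rule started on U0702u at 1, U1061u at 5001 and A0041p at 370001. They carried 0 methylated calls of 146, 115 and 104 observations, which allows levels of up to 2.5%, 3.16% and 3.48%. Mouse ES cells had 1 such window, in build NCBI37, on the unplaced sequence unkUn at 5495001 (70.6%). Rice, zebrafish and Arabidopsis shoots had no window with 100 CG observations.

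Neighbouring CG sites on a strand still shared much of their methylation 1 to 2 kb apart in Ciona. Across pairs of Ciona sites 1 to 30 bp apart the correlation of calls was 0.899, and at over 1000 and up to 2000 bp it was still 0.608. Arabidopsis flowers fell from 0.794 to 0.355 over the same distances, Arabidopsis shoots from 0.813 to 0.309 and the honey bee from 0.724 to 0.136. Rice fell from 0.747 to 0.196, poplar from 0.770 to 0.393 (SE 0.0652) and Chlamydomonas from 0.686 to 0.284. Mouse ES cells had 0.577 at over 1000 bp, but with an SE of 0.566 from 567 pairs, so they were not ranked against Ciona. In met1 flowers the correlation was 0.476 at 1 to 30 bp and 0.0202 at over 1000 bp, and in vim1 vim2 vim3 flowers it was 0.449 and 0.0234. The files do not tell which calls came from the same molecule. These correlations are across sites within 1 library, and sites are not independent replicates. For pairs more than 100 and up to 2000 bp apart, wild-type zebrafish embryos gave a correlation of 0.0165 (block jackknife SE 0.0956, 176 pairs), so no relation was detectable at this depth.

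Methylation fell with the number of CG sites in the invertebrates. From the quintile of 5-kb windows with the fewest recognised CG sites to the quintile with the most, Ciona fell from 53.1% to 25.2% and the honey bee from 6.15% to 0.784%. Arabidopsis shoots fell from 31.4% to 17.7%, although the fall in shoots was smaller in 2-kb windows, at -6.49 points (SE 0.711). Arabidopsis flowers went from 35.6% to 37.5%, a change of 1.93 points with a jackknife SE of 3.55, and of 4.36 points (SE 1.66) in 2-kb windows. Rice rose from 52.4% to 81.7%, poplar from 47.2% to 84.8% and Chlamydomonas from 5.75% to 55.4%. Wild-type zebrafish embryos rose from 74.0% to 87.7%, and mouse ES cells went from 82.0% to 79.8%, a change of -2.15 points with an SE of 2.13. The number of recognised sites also depends on coverage. With windows ranked by the share of CG among recognised CG, CCG and CWG sites, the change in Chlamydomonas was 2.70 points (SE 3.53), while Ciona changed by -39.5 points, the honey bee by -9.11, Arabidopsis shoots by -3.12 (SE 1.22), rice by 27.1 and poplar by 11.4.

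Both strands of a CG site were usually methylated together in the plant and invertebrate wild types. Of sites with a methylated call on either strand, both strands were methylated in 89.3% in poplar, 86.9% in rice, 82.9% in Ciona, 72.0% in Arabidopsis flowers, 71.1% in Arabidopsis shoots and 59.8% in the honey bee. Independent strands would have given 44.3%, 50.1%, 21.4%, 17.6%, 12.0% and 1.12%. Chlamydomonas showed 34.4% against 13.1% for independent strands. This value depended on depth, since it was 85.6% against 72.7% at sites with at least 3 observations per strand, and 26.3% at sites with at most 10 observations. In wild-type zebrafish embryos the share was 80.8% against 72.8%, and in mouse ES cells 74.4% against 70.3%. The CWG sites of poplar were also symmetric, with 79.4% against 17.1%. So were those of rice, with 59.0% against 11.7%, and those of Arabidopsis flowers, with 40.1% against 5.02%. In Chlamydomonas the CWG share was only 7.1% against 4.51%. In met1 flowers the CG share fell to 4.33% (interval 3.50 to 5.29%) and in vim1 vim2 vim3 flowers to 6.32% (5.28 to 7.48%), while their CWG shares were 37.6% and 45.6%. Independent strands would have given 0.56% and 0.76% in CG, so the remaining CG calls still agreed more than that. Since such shares fall with the level, the correlation of both strands is also given. It was 0.073 in met1 and 0.105 in vim1 vim2 vim3, against 0.767 in wild-type flowers. At CG sites with at least 3 observations per strand, the share was 5% (0.127 to 24.9%) in met1 and 25% (12.7 to 41.2%) in vim1 vim2 vim3, against 86.0% in wild-type flowers. In uhrf1 ES cells the CG share was 13% (10.3 to 16.1%) against 11.2% for independent strands, a difference within counting error. In uhrf1 zebrafish embryos it was 33.8% (29.4 to 38.3%) against 26.5%. The files do not link the calls of both strands to 1 molecule, so these shares do not show single molecules with 1 methylated strand.

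**Figure D3:**
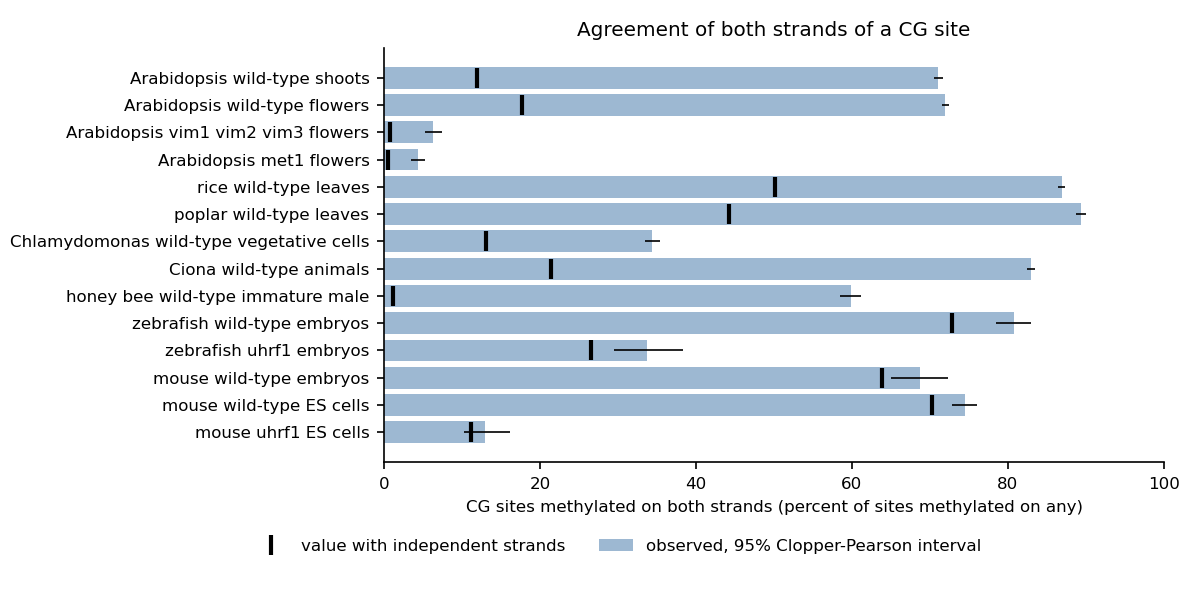
Share of CG sites methylated on both strands among sites methylated on any (percent, x axis) per library, as bars with exact 95% intervals, and the share that independent strands would give, as ticks. Wild-type Arabidopsis flowers reach 72.0% and met1 flowers 4.33%.

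Met1 and vim1 vim2 vim3 flowers lacked nearly all CG methylation of wild-type flowers, and the question was whether both mutants lose the same methylation. CG methylation fell from 31.3% in wild-type flowers to 1.45% in met1 and 1.61% in vim1 vim2 vim3 flowers. CCG methylation fell from 9.99% to 1.67% in met1 and 2.05% in vim1 vim2 vim3. CWG methylation did not fall and was 12.2% in met1 and 13.5% in vim1 vim2 vim3, against 10.2% in wild type. CCC methylation was 0.929% in met1 and 1.11% in vim1 vim2 vim3, against 0.943% in wild type. The chloroplast background in CG was 0.607% in wild type, 0.334% in met1 and 0.494% in vim1 vim2 vim3. By a block jackknife over 1-Mb blocks, the CG difference from wild type was -29.8 points (SE 2.40) in met1 and -29.7 points (SE 2.44) in vim1 vim2 vim3. The CWG difference was 1.99 points (SE 0.430) in met1 and 3.29 points (SE 0.546) in vim1 vim2 vim3. The CCC difference of met1, -0.0146 points (SE 0.0917), was within its error, although regions went both ways. Met1 minus vim1 vim2 vim3 was -0.165 points in CG (SE 0.0715), and this sign was not stable, since it was 0.0774 points (SE 0.2) at CG sites observed in both libraries and 0.345 points at sites with at least 4 observations. All 3 flower libraries were run on the same flow cell, per the file names.

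The CG loss reached nearly all windows with high CG methylation in wild type and most of those with intermediate methylation. In 2-kb windows with at least 20 CG observations in both libraries, met1 was lower than wild type in 1189 of 2831 windows and higher in 1. The vim1 vim2 vim3 flowers were lower in 870 of 1988 windows and higher in 0. Of the 583 met1 windows with over 80% CG methylation in wild type, 582 were lower, and their level fell from 90.1% to 6.91%. Of the 470 such vim1 vim2 vim3 windows all 470 were lower, and their level fell from 89.99% to 5.55%. Of windows with 20 to 80% in wild type, 607 of 667 were called lower in met1 and 400 of 444 in vim1 vim2 vim3. Windows were called by Fisher's exact test, two-sided, with Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 20 points. This compares 2 libraries, not 2 conditions. On simulated data the met1 test recovered 100% of falls of 60 points and 38% of falls of 30 points, and called 1 unchanged window of 2831.

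The largest falls ran from full methylation to none. On chromosome 1, the windows 13834001 to 13836000, 15660001 to 15662000 and 21608001 to 21610000 (TAIR9) had 100% CG methylation in wild type, from 23, 73 and 38 observations. In met1 they had 0 methylated calls of 34, 22 and 21 observations, with adjusted exact p of 2.5e-15, 1.2e-20 and 2.6e-15. The window 13834001 to 13836000 was also among the largest falls in vim1 vim2 vim3 flowers, with 0 of 35 and an adjusted exact p of 1.2e-15. The other two there were 19660001 to 19662000 on chromosome 1 (0 of 31, adjusted exact p 2e-14) and 5304001 to 5306000 on chromosome 2 (0 of 41, adjusted exact p 8.3e-17), both at 100% in wild type. The single rise was on chromosome 5 from 8180001 to 8182000, where met1 had 40.4% and wild type 11.1% (adjusted exact p 0.0089).

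Met1 and vim1 vim2 vim3 flowers both lost CG methylation in most windows that had it in wild type. Of 1543 windows tested in both comparisons, met1 was lower in 663 and vim1 vim2 vim3 in 652, and 644 were shared. All of these lay among the 682 windows with at least 20% CG methylation in wild type, where independent lists of these sizes would share 633.8, so the overlap follows largely from the near complete loss in each mutant. Unchanged libraries drawn against the same wild type, with independent calls, gave a mean of 0 shared calls in 100 draws. The thresholds on p and on the difference made this nearly certain, so no conclusion is drawn from it. Both comparisons used 1 wild-type library, so the lists are not independent. Tested directly against each other over 2853 windows, a test added after the data were seen, met1 was higher than vim1 vim2 vim3 in 2 windows and lower in 0. These were chromosome 2 from 6548001 to 6550000 (56.3% against 0 of 21, adjusted exact p 0.011) and chromosome 3 from 15246001 to 15248000 (23.1% against 3.04%, adjusted exact p 5e-05). With each site counted once by majority, which left 965 windows to test, 0 were called.

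CHG methylation changed in both directions at single windows of the mutants. CHG here joins the recognised CCG and CWG sites. These went opposite ways over the genome. CCG fell from 9.99% to 1.67% in met1 and 2.05% in vim1 vim2 vim3, while CWG went from 10.2% to 12.2% and 13.5%. CCG and CWG were not tested apart in windows, so neither called falls nor shared falls can be assigned to 1 of them. Met1 was lower in 132 and higher in 24 of 3456 windows, and vim1 vim2 vim3 was lower in 62 and higher in 16 of 1999. The largest rises in met1 were all on chromosome 1, at 10686001 to 10688000 (0% to 65.6%, adjusted exact p 3.3e-09), 26034001 to 26036000 (0% to 64.0%, adjusted exact p 1.7e-05) and 8968001 to 8970000 (0% to 55.5%, adjusted exact p 5.2e-09). Wild type had 27, 27 and 38 observations in these windows. The largest falls in met1 were chromosome 3 from 15246001 to 15248000 (86.2% to 6.00%), chromosome 2 from 7008001 to 7010000 (80% to 0 of 23) and chromosome 2 from 6716001 to 6718000 (80.8% to 4.76%). In vim1 vim2 vim3 the window at 6716001 fell to 0.730% (adjusted exact p 1.5e-34), chromosome 3 from 15576001 to 15578000 fell from 70.5% to 0 of 28, and chromosome 1 from 7072001 to 7074000 fell from 67.7% to 0 of 32. The largest rises in vim1 vim2 vim3 were chromosome 5 from 20772001 to 20774000 (19.2% to 79.2%), chromosome 1 from 12994001 to 12996000 (24.5% to 82.5%) and chromosome 5 from 9252001 to 9254000 (36.7% to 89.3%). Of 1392 windows tested in both comparisons, 51 falls were shared, from 95 in met1 and 57 in vim1 vim2 vim3. Among the 464 of these windows with at least 20% CHG methylation in wild type, independent lists would share 11.7, although both lists rest on the same wild-type library. Of 9 rises in met1 and 12 in vim1 vim2 vim3, 2 were shared, where independent lists would share 0.0776, again with 1 wild-type library behind both. For CHH, 34 windows could be tested in met1 and 33 in vim1 vim2 vim3, and 0 were called in either. Without the minimum difference of 20 points, 3 windows were higher in met1 and 6 in vim1 vim2 vim3, and 0 were lower.

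CG methylation fell along all chromosomes in the mutants, and the change in CWG methylation differed with the wild-type CG level of the region. The 3 regions of 1 Mb with the highest wild-type CG methylation were chromosome 4 from 3000001 to 4000000 (83.7%), chromosome 5 from 12000001 to 13000000 (83.6%) and chromosome 3 from 14000001 to 15000000 (81.7%). These 1-Mb regions were chosen after their values were seen. In met1 they carried at most 10.1%, the value of the chromosome 3 region, and in vim1 vim2 vim3 at most 7.28%, again on chromosome 3. The chromosome 3 and 4 regions were still the highest of their chromosome in both mutants, and the chromosome 5 region in met1. CWG methylation rose in both mutants where CG methylation had been low, and in vim1 vim2 vim3 also where CG methylation had been high. In the quintile of 1-Mb windows with the least wild-type CG methylation it went from 1.86% to 4.36% in met1 and 3.22% in vim1 vim2 vim3, and all 25 windows rose in both mutants. In the quintile with the most it went from 39.3% to 37.7% in met1, with 13 of 25 windows higher, and to 43.8% in vim1 vim2 vim3, with 21 of 25 higher. In vim1 vim2 vim3 the rise in CWG was larger in points there (4.495) than in the quintile with the least (1.361). CCG methylation in the quintile with the most fell from 28.2% to 4.57% in met1 and 5.02% in vim1 vim2 vim3. CCC methylation there went from 1.34% to 2.22% in met1, with 13 of 25 windows higher, and to 2.39% in vim1 vim2 vim3, with 21 of 25 higher. In the quintile with the least it went from 0.780% to 0.474% in met1, with 4 of 25 windows higher, and to 0.637% in vim1 vim2 vim3, with 7 of 25 higher.

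**Figure D4:**
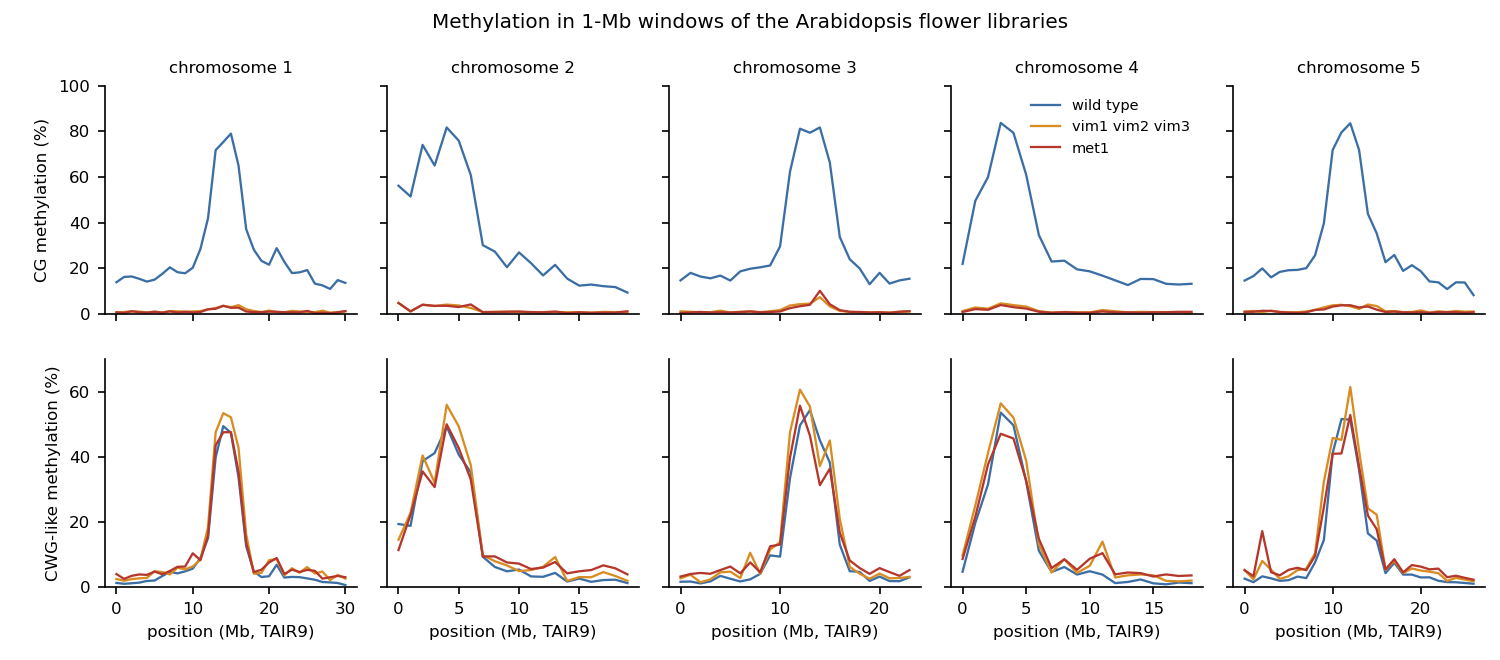
CG (top) and CWG (bottom) methylation in percent along the 5 Arabidopsis chromosomes in 1-Mb windows (x axis in Mb, TAIR9) for wild-type, met1 and vim1 vim2 vim3 flowers. The wild-type CG peak of 83.7% on chromosome 4 is 3.85% in met1 and 4.59% in vim1 vim2 vim3, while CWG peaks are seen in all 3 libraries.

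CG methylation was lower in uhrf1 than in wild-type zebrafish embryos, and the question was whether UHRF1 is needed for CG methylation in vertebrates. CG methylation was 83.1% in wild-type and 42.8% in uhrf1 embryos. The difference was -40.3 points (jackknife SE 1.44). At the CG sites observed in both libraries it was smaller, at -24.7 points (SE 5.35; 62.0% against 86.7%, from as few as 129 observations). CG sites were too sparse for windows, since only 2 windows of 100 kb could be tested and 0 were called. The methylated share of all cytosines was therefore compared in 1-Mb windows, an addition made after the data were seen. It was lower in uhrf1 embryos in all 1130 windows, and in 1110 of them the adjusted exact p was under 0.05 (Fisher's exact test, two-sided). The median ratio of uhrf1 to wild type was 0.492, with 0.383 at the 10th and 0.631 at the 90th percentile of windows. The standard deviation of the log ratio was 0.199, against 0.128 from counting alone, so part of this range is counting error. Both the counting value and the exact test treat calls as independent, so counting error may be larger. In uhrf1 embryos 12.06% of covered cytosines were read more than once, against 2.189% in wild type. The windows named next are the extremes of the range. The lowest ratios were on chromosome 21 from 2000001 to 3000000 (16.9% to 4.21%) and on chromosome 14 from 53000001 to 54000000 (13.9% to 3.63%) and from 15000001 to 16000000 (11.2% to 3.12%). The highest ratio was on chromosome 4 from 34000001 to 35000000, where both libraries had 17.0% (adjusted exact p 1). Coordinates are in Sanger Zv7. CCC methylation was 1.16% in uhrf1 embryos and 0.736% in wild type, which is opposite to the change in CG. The ratio of uhrf1 to wild type was 0.515 at recognised CG sites. It was 0.432 there when weighted to opposite-strand coverage, and 0.482 over all cytosines, which include non-CG sites. The pooled CG ratio and difference are thus of recognised sites, and may understate the loss over all CG sites. The libraries were run on different machines and dates, per the file names, so batch and genotype cannot be told apart.

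CG methylation was also lower in uhrf1 than in wild-type mouse ES cells, by more points than in zebrafish, although the difference between the species was not tested. CG methylation was 81.9% in wild-type and 19.3% in uhrf1 ES cells. CWG methylation was 1.77% and 1.76%, a difference of -0.00892 points with an SE of 0.0834. This pools 2 uhrf1 lanes that differed, with 1.99% in lane 1 and 1.12% in lane 2, against 1.81% and 1.71% in the wild-type lanes. CCC methylation was 0.683% in uhrf1 against 0.483% in wild type when pooled (difference 0.20 points, SE 0.018). The sign depended on the flow cell, with 0.824% against 0.568% in lane 1 and 0.312% against 0.371% in lane 2. The CG difference was -62.6 points (jackknife SE 0.699). Each library had 2 lanes, and lanes of the same number shared a flow cell. The difference was -61.5 points within the first flow cell and -66.4 points within the second. The uhrf1 lanes themselves differed, with 21.2% in lane 1 and 14.4% in lane 2, and the labels do not say whether both held the same preparation of DNA. Of 8 testable 100-kb windows 7 were lower, and the largest falls were on unkUn from 3900001 to 4000000 (82.9% to 9.09%) and from 5200001 to 5300000 (81.0% to 8.43%), and on chromosome 11 from 3000001 to 3100000 (87.3% to 24.2%), in NCBI37. Over all cytosines in 1-Mb windows, uhrf1 was lower in all 2532 windows, and in 2516 the adjusted exact p was under 0.05. The median ratio was 0.431, with 0.339 at the 10th and 0.546 at the 90th percentile. All cytosines include non-CG sites, and at recognised CG sites the ratio was lower, at 0.2355. Over the 1-Mb windows, the standard deviation of the log ratio was 0.193, against 0.135 from counting alone. Part of the range is therefore counting error, and the counting value again treats calls as independent. The ratio was lowest on chromosome 8 from 19000001 to 20000000 (4.45% to 0.765%) and highest on chromosome 14 from 36000001 to 37000000 (2.02% to 1.80%, adjusted exact p 0.52).

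**Figure D5:**
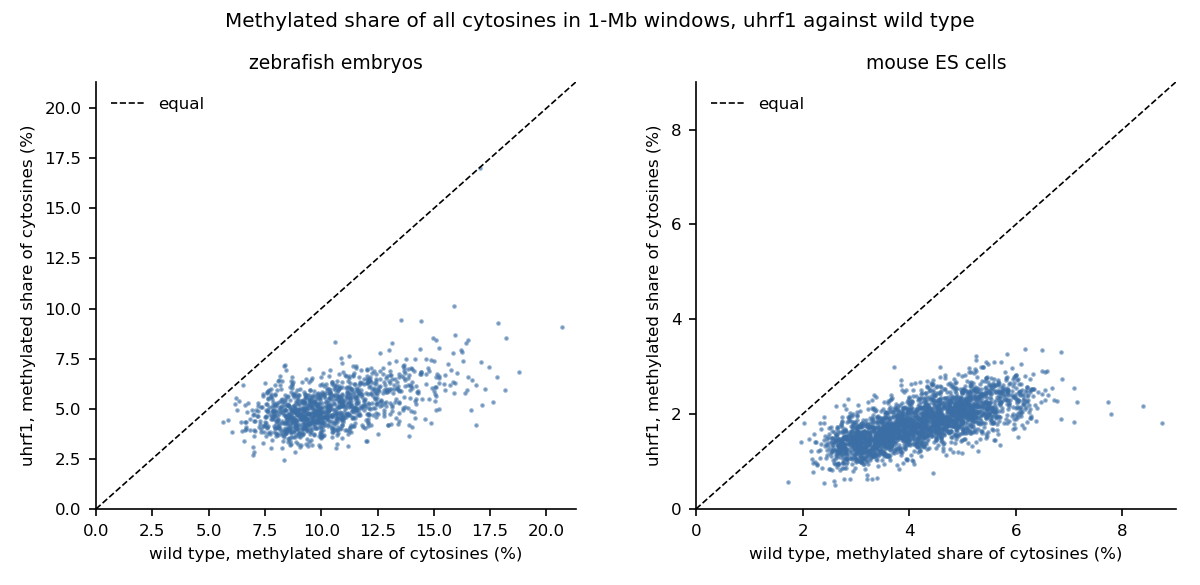
Methylated share of all cytosines (percent) in 1-Mb windows in wild type (x axis) and uhrf1 (y axis) for zebrafish embryos and mouse ES cells, with the line of equal values. All windows lie below the line, with median ratios of 0.492 in zebrafish and 0.431 in mouse. These are over all cytosines, and at recognised CG sites the ratios were 0.515 and 0.2355.

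Mouse embryos and wild-type ES cells both carried high CG methylation, and ES cells had more methylated calls in CWG and CCC. CG methylation was 77.1% in embryos and 81.9% in ES cells, a difference of -4.74 points (jackknife SE 0.670). The sign differed at CG sites observed in both libraries, where embryos were higher by 1.85 points, but with an SE of 8.63 from as few as 252 observations. The CWG level was 0.423% in embryos and 1.77% in ES cells, and the CCC level was 0.220% and 0.483%. CCC serves as the background of calls in animals, and it was 0.568% and 0.371% in the 2 ES cell lanes. The CCC difference is therefore not shown to be methylation. CCG methylation was 0.86% and 0.902%, a difference of -0.0424 points (SE 0.355) whose sign changed to 0.164 points when weighted to opposite-strand coverage. The CWG difference was -1.34 points (SE 0.0665), larger than the CCC difference of -0.263 points (SE 0.0149). Tissue, strain and flow cell differed together, so they cannot be told apart.

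Arabidopsis shoots carried less methylation than flowers in CG, CCG and CWG. CG methylation was 21.1% in shoots and 31.3% in flowers, CCG methylation 4.85% and 9.99%, and CWG methylation 5.72% and 10.2%. The CG difference was -10.2 points (jackknife SE 3.0). It was -6.89 points when weighted to opposite-strand coverage, -6.35 points with each site counted once and -43.7 points at sites with at least 4 observations, so its size depended strongly on the sites used. Strand agreement was alike, with 71.1% in shoots and 72.0% in flowers. Single cytosines were covered up to 11 times in shoots and up to 10038 times in flowers, and the sources do not say whether duplicate reads were treated alike. The files of shoots use another genome build and come from other runs, so tissue and batch cannot be told apart and no region was compared.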

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

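No test in this part was chosen after its result was seen. Organelle sequences are outside the comparisons, and those given here had a CG level whose exact 95% interval lay above that of CCC in the same sequence.

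The mitochondrial sequence of wild-type Arabidopsis carried CG methylation calls that met1 flowers lacked. Its CG level was 21.9% in shoots (CCC 0.170%) and 13.8% in wild-type flowers (CCC 0.726%), against 0.783% in met1 flowers (CCC 0.355%). A failure of bisulfite conversion would mark CCC like CG, but the CCC level was 0.775% of the CG level in shoots (interval 0.222 to 2.07%) and 5.27% in flowers (3.79 to 7.11%), which argues against it. The met1 level was 5.69% of the wild-type flower level (5.04 to 6.39%), as at nuclear CG sites, so reads of a methylated nuclear copy of mitochondrial DNA are a candidate explanation. CG observations there were 37563 in met1 and 19239 in wild-type flowers, so this ratio also depends on the amount of mitochondrial DNA read. In vim1 vim2 vim3 flowers the CG level was 0.954%. CCG went from 6.38% in wild-type flowers to 0.769% in met1 and 0.695% in vim1 vim2 vim3. CWG went from 8.60% to 3.84% and 4.84%. Methylation of the mitochondrial DNA itself by MET1 stays open for CG, but copying of CG methylation alone would not account for the CWG calls. No biological explanation was tested.

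Other organelle sequences gave smaller values. The chloroplast CG level was 0.454% in Arabidopsis shoots (CCC 0.13%) and 0.607% in wild-type flowers (CCC 0.450%). Rice mitochondria had 1.77% in CG from 790 observations and 0 methylated calls of 633 in CCC, which allows up to 0.581%. The Chlamydomonas chloroplast had 2.64% in CG (CCC 0.238%) and its mitochondrion 0.335% (CCC 0.0492%). No explanation was tested for these values.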

How the results depend on the processing

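The tests chosen only after the result was seen were the weighting by opposite-strand coverage, the CG sites observed in both libraries, all cytosines in 1-Mb windows, ranking by the share of CG sites, the limit of at most 10 observations on strand agreement, the window test of met1 against vim1 vim2 vim3 and its alternatives, and the overlap of the windows of both mutants. Of 319 values under an alternative, 141 stayed within the 95% interval of the reported value (or, for counts of windows, within a factor of 1.5), 173 moved beyond it and 5 changed sign. For CG levels and their differences this interval was of counting error only, and for differences it was narrower than the block jackknife interval. Values counted as moved can thus lie within the jackknife interval. Met1 minus wild-type flowers, weighted by opposite-strand coverage, was -25.9 points and counted as moved. The jackknife interval of that difference ran from -34.5 to -25.1 points. A further 2 values, both of mouse embryos and neither distinguishable from 0 as reported, changed sign within their own interval, from 0.12 to -0.0901 for the correlation of neighbours and from -0.777 to 0.332 points for the density of CG sites. The CG differences of met1, vim1 vim2 vim3 and both uhrf1 libraries from wild type, and of shoots from flowers, kept their sign under all alternatives run.

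The small CG difference between met1 and vim1 vim2 vim3 changed sign under 2 alternatives, and that between mouse embryos and ES cells under 1. At sites with at least 4 observations, the differences were -59.3 points for met1 minus wild-type flowers, -59.6 points for vim1 vim2 vim3 minus wild-type flowers, 0.345 points for met1 minus vim1 vim2 vim3, -63.9 points for uhrf1 minus wild-type ES cells and -43.7 points for shoots minus flowers. At CG sites observed in both libraries, they were -35.1 points for met1 minus wild-type flowers, -36.5 points for vim1 vim2 vim3 minus wild-type flowers, 0.0774 points for met1 minus vim1 vim2 vim3, -24.7 points for uhrf1 minus wild-type zebrafish, -58.0 points for uhrf1 minus wild-type ES cells and 1.85 points for mouse embryos minus ES cells. Both alternatives use fewer sites by construction, and beyond that the cause was not tested.

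Counting each site and strand once gave CG levels of 21.4% in shoots, 27.7% in wild-type flowers, 1.21% in vim1 vim2 vim3, 0.997% in met1, 61.4% in poplar, 23.1% in Chlamydomonas, 35.2% in Ciona and 2.21% in honey bee. The differences were -26.7 points for met1 minus wild-type flowers, -26.5 points for vim1 vim2 vim3 minus wild-type flowers, -0.210 points for met1 minus vim1 vim2 vim3 and -6.35 points for shoots minus flowers. Keeping sites with at least 4 observations gave levels of 19.1% in shoots, 62.8% in wild-type flowers, 3.16% in vim1 vim2 vim3, 3.50% in met1, 62.3% in rice, 97.6% in poplar, 59.6% in Chlamydomonas, 39.3% in Ciona, 2.46% in honey bee, 73.9% in wild-type ES cells and 10% in uhrf1 ES cells. Without sites above 10 times the median coverage, levels were 29.1% in wild-type flowers, 1.38% in vim1 vim2 vim3, 1.13% in met1 and 28.8% in Chlamydomonas, and differences -27.9 points for met1 minus wild-type flowers, -27.7 points for vim1 vim2 vim3 minus wild-type flowers, -0.253 points for met1 minus vim1 vim2 vim3 and -8.01 points for shoots minus flowers. Subtracting background gave levels of 20.7% in shoots, 30.8% in wild-type flowers, 1.16% in vim1 vim2 vim3, 1.12% in met1, 66.5% in rice, 67.0% in poplar and 2.03% in honey bee, with differences of -29.6 points for met1 minus wild-type flowers, -0.0433 points for met1 minus vim1 vim2 vim3 and -10.0 points for shoots minus flowers. Contexts from each library alone gave levels of 35.2% in wild-type flowers, 2.38% in vim1 vim2 vim3, 1.97% in met1, 85.1% in wild-type zebrafish and 40.9% in uhrf1 zebrafish. The differences were then -33.2 points for met1 minus wild-type flowers, -32.8 points for vim1 vim2 vim3 minus wild-type flowers, -0.413 points for met1 minus vim1 vim2 vim3, -44.2 points for uhrf1 minus wild-type zebrafish and -14.1 points for shoots minus flowers. Lane 1 alone gave 69.6% in poplar, 44.0% in Chlamydomonas, 82.7% in wild-type ES cells and 21.2% in uhrf1 ES cells, and -61.5 points for uhrf1 minus wild-type ES cells. Lane 2 alone gave 65.6% in poplar, 41.2% in Chlamydomonas, 80.8% in wild-type ES cells and 14.4% in uhrf1 ES cells, and -66.4 points for uhrf1 minus wild-type ES cells. Weighting by opposite-strand coverage gave 20.1% in shoots, 26.9% in wild-type flowers, 1.18% in vim1 vim2 vim3, 1.01% in met1, 53.0% in rice, 46.5% in poplar, 8.57% in Chlamydomonas, 2.05% in honey bee, 78.7% in wild-type zebrafish, 34% in uhrf1 zebrafish, 80.3% in mouse embryos, 83.5% in wild-type ES cells and 20.2% in uhrf1 ES cells. The weighted differences were -25.9 points for met1 minus wild-type flowers, -25.8 points for vim1 vim2 vim3 minus wild-type flowers, -44.7 points for uhrf1 minus wild-type zebrafish, -3.21 points for mouse embryos minus ES cells and -6.89 points for shoots minus flowers. Subtracting background lowers levels by construction, and for the other changes the cause was not tested.

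The reported counts of called windows were 1189 lower and 1 higher in CG for met1, 870 lower and 0 higher in CG for vim1 vim2 vim3, and 0 lower and 2 higher in CG for met1 against vim1 vim2 vim3. In CHG they were 132 lower and 24 higher for met1 and 62 lower and 16 higher for vim1 vim2 vim3, in CHH they were 0, and in CG of uhrf1 they were 7 lower in mouse ES cells and 0 in zebrafish. With at least 10 observations, calls were 5390 lower in CG for met1, 4167 lower in CG for vim1 vim2 vim3, 49 higher in CHG for met1 and 25 higher in CHG for vim1 vim2 vim3. With at least 50 they were 105 lower and 0 higher in CG for met1, 97 lower in CG for vim1 vim2 vim3, 18 lower and 1 higher in CHG for met1, 23 lower and 3 higher in CHG for vim1 vim2 vim3, 1 lower and 1 higher in CG for met1 against vim1 vim2 vim3 and 3 lower in CG for uhrf1 mouse ES cells. Each site counted once by majority left fewer observations and gave 380 lower and 0 higher in CG for met1, 262 lower and 1 higher in CG for vim1 vim2 vim3, 41 lower and 6 higher in CHG for met1, 16 lower and 3 higher in CHG for vim1 vim2 vim3, 0 higher in CG for met1 against vim1 vim2 vim3 and 2 lower in CG for uhrf1 mouse ES cells. Without a minimum difference, calls were 1 higher in CG for vim1 vim2 vim3, 3 higher in CHH for met1, 6 higher in CHH for vim1 vim2 vim3 and 4 higher in CG for met1 against vim1 vim2 vim3. With a minimum of 40 points they were 0 higher in CG for met1, 15 higher in CHG for met1 and 1 higher in CG for met1 against vim1 vim2 vim3. Thinning the deeper library gave 1 lower in CG for met1 against vim1 vim2 vim3. In 10-kb windows, calls were 5134 lower and 0 higher in CG for met1. With all cytosines in 1-Mb windows they were 1110 lower for uhrf1 zebrafish and 2516 lower for uhrf1 mouse ES cells. A higher minimum of observations by construction leaves fewer windows to test, and a lower minimum leaves more. For single calls that came or went the cause was not tested.

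The share of windows between 20 and 80% CG methylation was higher in larger windows of Ciona and rice. In 100-kb windows it was 0.0841% in met1, 0% in vim1 vim2 vim3, 44.4% in wild-type flowers, 30.5% in shoots, 25.3% in Chlamydomonas, 71.4% in Ciona, 4.67% in honey bee, 19.5% in poplar and 62.3% in rice. With at least 50 observations it was 1.5% in met1, 3.48% in vim1 vim2 vim3, 33.7% in wild-type flowers, 9.09% in shoots, 30% in Ciona, 0.481% in honey bee and 0% in poplar. With exactly 20 observations drawn per window it was 0.851% in met1, 1.38% in vim1 vim2 vim3, 39.5% in wild-type flowers and 27.7% in shoots. Larger windows also bring in other parts of the genome, and the cause of these changes was not tested.

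The change from the quintile with the fewest to that with the most CG sites was, in 2-kb windows, -6.49 points in shoots, -22.6 points in Ciona, 31.5 points in rice and 23.6 points in uhrf1 zebrafish. Ranked by the share of CG sites it was -3.12 points in shoots, 2.70 points in Chlamydomonas, -39.5 points in Ciona, -9.11 points in honey bee, 11.4 points in poplar and 27.1 points in rice. Correlations of neighbours more than 100 bp apart were 0.0297 in met1, 0.0394 in vim1 vim2 vim3, 0.432 in wild-type flowers, 0.372 in shoots, 0.26 in Chlamydomonas, 0.680 in Ciona, 0.211 in honey bee, -0.0377 in uhrf1 ES cells, 0.485 in poplar, 0.312 in rice, -0.0617 in uhrf1 zebrafish and 0.0165 in wild-type zebrafish. They leave out close pairs, which by construction lowers correlations that fall with distance. The signs in both uhrf1 libraries differ from those over all pairs, but these values are within their SE of 0 (0.101 in ES cells and 0.148 in zebrafish). Agreement of both strands at sites with at least 3 observations per strand was 25% in vim1 vim2 vim3, 86.0% in wild-type flowers, 84.4% in shoots, 85.6% in Chlamydomonas, 81.8% in Ciona, 80% in honey bee, 98.8% in poplar and 95% in rice. With at most 10 observations per site it was 5.08% in vim1 vim2 vim3 and 26.3% in Chlamydomonas. For the changes in density and strand agreement the cause was not tested.

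Depth limited the alternatives. Zebrafish and mouse embryos had too few CG sites with 4 observations, no zebrafish window of 100 kb had 50 CG observations, no CHH window was left with each site counted once, and strand agreement by majority could not be computed for zebrafish and mouse. Shoots and flowers share no coordinates, so no common sites were compared. Contexts from a reference, genes of at least 2 kb, gene bodies without their first 500 bp and other minimums for genes were not run, for want of a reference of the same build.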

Other observations

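The tests of background calls, of different parts of the genome and of wild-type DNA in the uhrf1 lanes, and the comparisons of lanes by window were chosen only after the result was seen, and the other tests of this part were not.

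Both lanes of the mouse uhrf1 ES cells were deposited as 1 sample, without saying whether they held the same preparation of DNA, and they differed in CG methylation, with 21.2% in lane 1 and 14.4% in lane 2. Background calls would raise CCC by as many points as CG, but the CCC difference was 7.57% of the CG difference (interval 6.11 to 9.88%), and at CG sites read once the difference was 94.3% of that at all sites (68.0 to 120.4%), which argues against background calls and against duplicates. With the lanes compared at CG sites within the same 1-Mb window, the difference was 103.9% of that at all sites (74.4 to 133.4%), which argues against lanes that cover different 1-Mb parts of the genome. At the 113 sites read in both lanes it was 142.1%, but with an interval from 43.8 to 240.5%, so uneven coverage at a finer scale stays open. Wild-type DNA in lane 1 as the only cause could not be decided from CCC. The CCC level of lane 1 was 0.824% (0.790 to 0.859%). Lane 2 had 0.312% (0.278 to 0.348%) and the wild-type lane of the same flow cell as lane 1 had 0.568% (0.541 to 0.596%). A mixture cannot exceed both of its parts, but lane 2 was run on the other flow cell. The wild-type lane there had 0.371% in CCC, so CCC also varied between wild-type lanes. Lane 2 therefore need not give the CCC level of the uhrf1 part of lane 1. The CWG level of lane 1 was 1.99% (1.86 to 2.13%), against 1.12% in lane 2. It overlapped that of the wild-type lane of its flow cell, 1.81% (1.68 to 1.94%), and excludes nothing. Wild-type DNA in lane 1 stays open. Different preparations of DNA, cells at different stages of methylation loss, or several of these explanations acting together, may still lie behind the difference, and none was tested.

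The pooled CG levels of poplar, rice and Chlamydomonas rose with opposite-strand coverage, and pile-ups of reads on a small part of the genome are a candidate explanation. In poplar the level rose from 45.2% in the stratum of lowest coverage to 93.7% in that of highest coverage. Without 1-kb windows of dense reads the gap shrank to 48.7% of its size (44.2 to 53.2%) in poplar and to 27.9% (23.7 to 31.8%) in Chlamydomonas, so pile-ups and a real link of methylation to coverage cannot be told apart there, since the gap neither closed nor stayed. In rice 89.6% of the gap remained (88.8 to 90.4%), which argues against pile-ups as the cause in rice. The dense windows held 11.7% of poplar and 46.8% of Chlamydomonas observations in 3.53% and 14.3% of windows.

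Over all cytosines, the lanes of other libraries also differed in some windows of 1 Mb, which vary in depth between libraries. Of 2444 windows in wild-type mouse ES cells, 4 were higher and 0 lower in lane 1 by Fisher's exact test, and lane 1 was higher in 74.1% of windows. In Chlamydomonas 80 of 193 such windows were higher and 13 lower in lane 1, together 48.2%, and lane 1 was higher in 73.6% of windows. In uhrf1 ES cells 711 of 1822 were higher and 1 lower, together 39.1%, and lane 1 was higher in 96.7%. In poplar 22 of 420 were higher and 4 lower, and in the honey bee 41 of 1091 were higher and 15 lower. In shoots 2 of 121 were higher and 0 lower, and in Ciona 0 of 189 were called. In Arabidopsis shoots 1 of 858 windows of 10 kb was higher and 1 lower in CG in lane 1.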
